A study of Arabidopsis thaliana with 4 samples.

How the data were processed

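RNA was taken from 4 pools of 6 to 8 whole plantlets, 1 pool for each combination of genotype and temperature, per the labels' protocols. Per the labels' protocols, ribosomal RNA was removed with a duplex-specific nuclease, which cuts the most abundant double-stranded cDNA, RNA was broken with zinc, and libraries were sequenced as single reads of 100 bp. The nuclease can also lower other very abundant transcripts, so comparisons across genes of very different level are less certain than comparisons of the same gene between libraries. BWA 0.5.9 and the genome build TAIR10 are named in the submitters' processing notes. The counting tool and the use of strand are not given in the sources used here.

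The main deposited table holds a signal per exon entry, named RPM per the file headers and rounded by the authors to 2 decimals. It has 181379 entries for 25819 genes, without coordinates, and 132172 of them are distinct within their gene; the other 49207 repeat an exon shared by several transcripts. Since the columns sum to more than RPM can, from 1056660 to 1090380, the values were treated as a signal. Each value was a whole multiple of the worth of 1 read within the rounding for at least 99.9981% of values above 0 in the WT 20 °C library and for higher shares in the others. The steps, 0.0217 RPM in WT 20 °C, 0.0235 in WT 38 °C, 0.0134 in larp1 20 °C and 0.0223 in larp1 38 °C, gave the depth behind each library. The rounding is coarse against these steps, so no count model was fitted and the reads served for minimums and counting intervals. The column of the larp1 20 °C library carries a suffix that is not explained. The deposited gene tables hold, per the file headers, summed signal per gene and a ratio (fold) of 38 °C over 20 °C. The header of the authors' list up in larp1 only gives the inverse, 20 over 38, but all 152 of its folds equal 38 °C over 20 °C within 1% and were read so. The sums equalled, within 0.016 RPM, the sum of all entries with at least 1 RPM in any library for 677 of the 680 genes up in both genotypes and for every gene of the other lists.

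The gene value was the sum of the distinct entries of a gene, chosen after the structure of the table was seen and not set in the planned design, which assumed counts per gene. Overlapping alternative exons can count a read more than 1 time, so the counting intervals are too narrow. Log2 fold changes are of RPM plus the worth of 1 read in that library. Such folds understate the change of genes with few reads. A gene was compared when it had at least 50 reads in at least 1 of the libraries, and was called higher or lower when it differed at least 2-fold and its 95% counting interval, from a conditional binomial distribution of the reads, excluded no change. The difference of heat responses used a normal interval on the log2 scale from the 4 read counts. PCR copies are not independent molecules, so intervals cover counting error only. A gene with 0 reads in a library was given a bound at 3 reads of that library; the floor is 0.0651 RPM in WT 20 °C, 0.0704 in WT 38 °C, 0.0403 in larp1 20 °C and 0.0668 in larp1 38 °C.

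The lists of genes, among them heat shock proteins, mRNA decay factors, hormone responses and markers of root, flower and seed, and the rule for named genes were fixed before the data were examined. The rule took LARP1A, LARP1B and LARP1C, the 10 highest and 10 lowest called nuclear genes of each heat comparison, and 5 and 5 of each other comparison, with at least 100 reads in at least 1 library (of each genotype for the difference). It also took up to 4 members of each list, those with the largest fold of heat in WT, and its most abundant member. Members with 0 reads were few enough that placing them at their bound left the list medians of the heat and genotype comparisons as given; this was not done for the difference of heat responses. The seed list members OLEO2 and CRB were not analysed here. A list median was ranked among 10000 random lists of the same size, drawn within 20 bins of mean level. The draws take genes as independent, whereas members of a list can move together within 1 pool. A rank therefore describes these libraries and does not measure variation between libraries. Gene symbols came from these lists and from a name table of the TAIR10.1 assembly, in which 25408 genes were matched; no coordinates are given, because that table is of another release than the one named in the processing notes. For 669 genes the table's entry carries the name of another locus, and such overlapping genes are uncertain.

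Alternatives set before the data were examined were TMM and median-of-ratios scaling, totals of summed gene values without organelle genes or without the 100 highest genes, a minimum of 10 reads or none, a pseudocount of 0.5 RPM, other choices of the lowered genes, and a 3-fold threshold for the overlap. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The calling was tested on simulated reads for heat in WT with 200 changed genes: 98.5% of genes changed 2.5-fold were recovered and 1 of 18674 unchanged genes was called, and at 4-fold all 200 were recovered and 2 of 18653 unchanged genes were called. These simulations hold counting noise only.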

Results

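Transcript levels were measured by RNA-seq in whole Arabidopsis thaliana plantlets of the Columbia-0 accession, wild type (WT) or mutant for larp1. LARP1 is an RNA-binding protein of the La-related family. Plantlets 21 days old were moved for 15 min into liquid medium kept at 20 °C or warmed to 38 °C. The 4 groups, WT at 20 °C, WT at 38 °C, larp1 at 20 °C and larp1 at 38 °C, hold 1 library each. No difference given here therefore has a replicate check, no p-value is given, and each comparison is between libraries. Values are RPM (reads of a gene scaled to the library total) summed over the distinct exon entries of a gene. The RPM values rest on about 46065300 reads in the WT 20 °C library, 42608500 in WT 38 °C, 74419700 in larp1 20 °C and 44931500 in larp1 38 °C. Bracketed ranges are 95% intervals that cover counting error only.

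The gene named in the design was examined first. LARP1A (AT5G21160) stood at 37.1 RPM in WT and 9.21 RPM in larp1 at 20 °C, which is 24.8% of the WT level. At 38 °C it stood at 33.1 RPM in WT and 9.29 RPM in larp1, which is 28.1%. The remaining reads were uneven between the exon entries of the gene, whose positions are not given. At 20 °C, 8 exon entries held at least 50 reads in WT; in larp1, 5 of these lay under 25% of WT and 3 at 50% or more, with a range from 10.5% to 61.8%. The paralogs did not share the lower level: at 20 °C LARP1B (AT5G66100) stood at 14.4 RPM in WT and 13.4 RPM in larp1, and LARP1C (AT4G35890) at 44.6 and 44.4 RPM. At 38 °C LARP1B stood at 22.3 RPM in WT and 28.3 RPM in larp1, and LARP1C at 20.1 and 28.3 RPM.

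**Figure D1:**
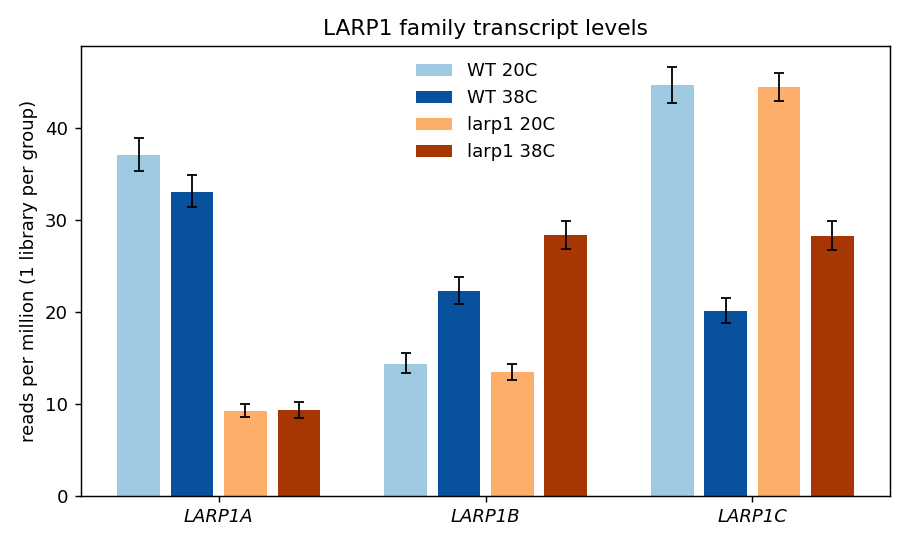
Level of LARP1A, LARP1B and LARP1C in RPM, with 1 bar per library; error bars are exact 95% Poisson intervals of the reads and cover counting error only. LARP1A stands at 37.1 and 33.1 RPM in the WT libraries and at 9.21 and 9.29 RPM in the larp1 libraries.

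The first comparison asks what 15 min at 38 °C did to the mRNA population of WT plantlets. Heat shock protein transcripts took up a larger share of the heated library, while a far larger number of other genes stood lower. The small heat shock proteins, chaperones that hold unfolding proteins in solution, together made up 0.0109% of reads at 20 °C and 3.15% at 38 °C. The HSP100, HSP90 and HSP70 chaperones with their co-chaperones went from 1.103% to 8.71%. Core histone transcripts were lower, and mitochondrion-encoded transcripts were higher. Of 19387 nuclear and organelle genes compared, 826 were at least 2-fold higher and 4840 at least 2-fold lower.

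Among the 17 small heat shock proteins, 16 were higher and 1 was lower, with a median log2 fold change of 8.93. HSP22-ER (AT4G10250) went from 0.24 to 959.6 RPM, a log2 fold change of 11.84 [11.13, 12.97]. HSP23.6-MTI (AT4G25200), the mitochondrial form, went from 0.50 to 1666 RPM. HSP17.6C-CI (AT1G53540) went from 0.98 to 2773 RPM, HSP17.4-CI (AT3G46230) had a log2 fold change of 11.26, and the plastid form HSP21 (AT4G27670) went from 0.19 to 470.8 RPM. HSP17.7-CII (AT5G12030) and HSP17.6-CII (AT5G12020) had log2 fold changes of 10.52 and 10.35, and HSP15.7 (AT5G37670) of 9.71. AT1G71000, which is not a member of this list, had 9.63. HSP17.8-CI (AT1G07400) had the highest mean level of the list and reached 4090 RPM. The member that was lower was HSP15.4 (AT4G21870), at 26.36 RPM at 20 °C and 11.99 RPM at 38 °C, named after its values were seen.

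Of the 27 large chaperones and co-chaperones, 20 were higher and 1 was lower, with a median log2 fold change of 2.34. HSP101 (AT1G74310), the disaggregase needed for acquired thermotolerance, went from 43.2 to 10466 RPM. HSP70-5 (AT1G16030) had a log2 fold change of 9.42, BAG6 (AT2G46240) of 8.32 and HOP3 (AT4G12400) of 8.01. HSC70-1 (AT5G02500), already at 5429 RPM at 20 °C, reached 10395 RPM. Heat shock factors, the transcription factors of the response, were divided: 7 of 18 were higher and 3 lower. HSFA7B (AT3G63350) had a log2 fold change of 9.53, HSFA2 (AT2G26150) of 7.48, HSFA7A (AT3G51910) of 6.58 and HSFB1 (AT4G36990) of 3.64. All 6 of the other early heat-induced genes were higher, among them the coactivator MBF1C (AT3G24500) at 6.85, the DnaJ-type AT2G20560 at 6.11 and DREB2A (AT5G05410) at 4.74. APX2 (AT3G09640), a cytosolic ascorbate peroxidase, was read 1 time at 20 °C and 1322 times at 38 °C, a ratio of 1429 [256.1, 56495].

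The genes lowest after heat in WT were of diverse kinds. MYB24 (AT5G40350), a transcription factor of stamen development, and ILL5 (AT1G51780) had 0 reads at 38 °C and were at least 40.4-fold and at least 38.2-fold lower, taking 3 reads in that library as the floor. DAD1 (AT2G44810), a lipase of jasmonate synthesis, was lower by a ratio of 103 [18.05, 4091]. The kinase AT3G08870 was lower by a ratio of 61.7 [20.8, 301.5], the receptor-like kinase AT2G24130 by 49.9 [13.5, 417.7], and IPT5 (AT5G19040), a cytokinin synthesis enzyme, by 33.3 [11.1, 164]. OFP16 (AT2G32100) had a log2 fold change of -5.56 [-7.48, -4.61], the SAUR-family gene AT2G21210 of -5.27 [-5.99, -4.73], ATCSLA15 (AT4G13410) of -4.65 and AT2G22200 of -4.59. The MYB24, HSP17.4-CI and DREB19 entries carry the name of a neighbouring locus in the deposited table, and reads of overlapping genes cannot be told apart without strand.

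Core histones were lower in 27 of 40 compared members and higher in 0, with a median log2 fold change of -1.40 against -0.46 for random lists of the same level. AT2G28720 had a log2 fold change of -3.17, AT3G53730 of -3.13, AT5G10390 of -3.07 and AT3G46320 of -3.01, while AT4G40040, the most abundant member, had -0.65. SAUR genes, a family responsive to auxin, were lower in 23 and higher in 7 of 47. AT2G45210 (SAUR36) had -3.98, AT4G22620 -3.67 and AT1G16510 -3.34. The SAUR median was -0.95 against -0.70 for random lists of the same level, just inside their central range of -0.96 to -0.44. The SAUR genes named here each have 1 distinct exon entry, and 50.7% of all such genes compared were lower in WT. Random lists were matched on level and not on the number of exon entries, so the histone median was not separated from that number either. Root markers were lower in 5 of 7 and higher in 1. SCR (AT3G54220) had a log2 fold change of -2.15, COBL9 (AT5G49270) of -1.89 and SHR (AT4G37650) of -1.61, and WOX5 (AT3G11260) of 2.01. The list median was -1.46 in WT, against -0.61 for random lists, and -0.72 in larp1, against -0.49. These markers stand for the share of root in the pools, and a smaller share in the heated WT pool cannot be told apart from heat. Of the mRNA decay list, 8 of 31 were lower, led by the deadenylases CAF1B (AT5G22250) at -1.84 and CAF1A (AT3G44260) at -1.62, with CCR4B (AT3G58580) at -1.25 and PAT1 (AT1G79090) at -1.18. PAB2 (AT4G34110), a poly(A)-binding protein, had -0.09, which turned positive under TMM and median-of-ratios scaling.

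Stress hormone genes moved in both directions. In the abscisic acid and dehydration list 2 of 12 were higher and 3 lower: NCED3 (AT3G14440), of abscisic acid synthesis, had a log2 fold change of 2.17, and RD29A (AT5G52310), RD29B (AT5G52300) and COR15A (AT2G42540) had -1.66, -1.53 and -1.40. In the rapid stress and touch list 4 of 14 were higher and 3 lower, with ZAT12 (AT5G59820) at 3.07, TCH3 (AT2G41100) going from 1518 to 3487 RPM, CBF1 (AT4G25490) at -2.16 and CBF3 (AT4G25480) at -1.39. Of 10 clock genes 1 was higher, PRR7 (AT5G02810) at 1.39, and 2 were lower, PRR5 (AT5G24470) at -1.60 and ELF4 (AT2G40080) at -1.39. In the defence list 1 of 6 was lower, VSP1 (AT5G24780) at -1.59.

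All 67 mitochondrion-encoded genes compared were higher, with a median log2 fold change of 3.65, and ATP1 (ATMG01190) went from 1.82 to 46.0 RPM. Chloroplast-encoded genes were higher in 7 of 46, with a median of 0.35; ATCG00120, an ATP synthase gene, had 1.45 and ATCG00480, the most abundant member, 0.19. Cytosolic ribosomal protein genes were lower in 2 of 40, with a median of -0.41 against -0.31 for random lists. AT5G67510 had -1.24, RPSAb (AT3G04770) -1.12 and RPL3A (AT1G43170) -0.40, the last positive under TMM and median-of-ratios scaling. Translation factors and nucleolar proteins were lower in 1 of 10, the nucleolar FIB2 (AT4G25630) at -1.21, and had a median of -0.35. None of the 26 nuclear photosynthesis genes passed 2-fold, and their median was -0.13. The medians of the ribosomal protein, translation, photosynthesis, clock and reference lists turned positive under TMM and median-of-ratios scaling. Of 11 reference genes UBQ10 (AT4G05320) was higher, at 1.66, and the list median was -0.00. Flower and seed markers had too few reads to be compared.

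The balance of higher and lower genes depends on the scaling. The median log2 fold change over all genes compared was -0.51 with RPM, and TMM and median-of-ratios scaling moved it by 0.51 and 0.53. The counts were then 1332 higher and 2183 lower with TMM and 1389 and 2100 with median-of-ratios, so that higher genes made up 37.9% and 39.8% of the calls in place of 14.6%. Relative to random lists of the same level, a position that no scaling changes, the histone median was 0.94 lower, the small heat shock protein median 9.16 higher and the mitochondrial median 4.44 higher.

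**Figure D2:**
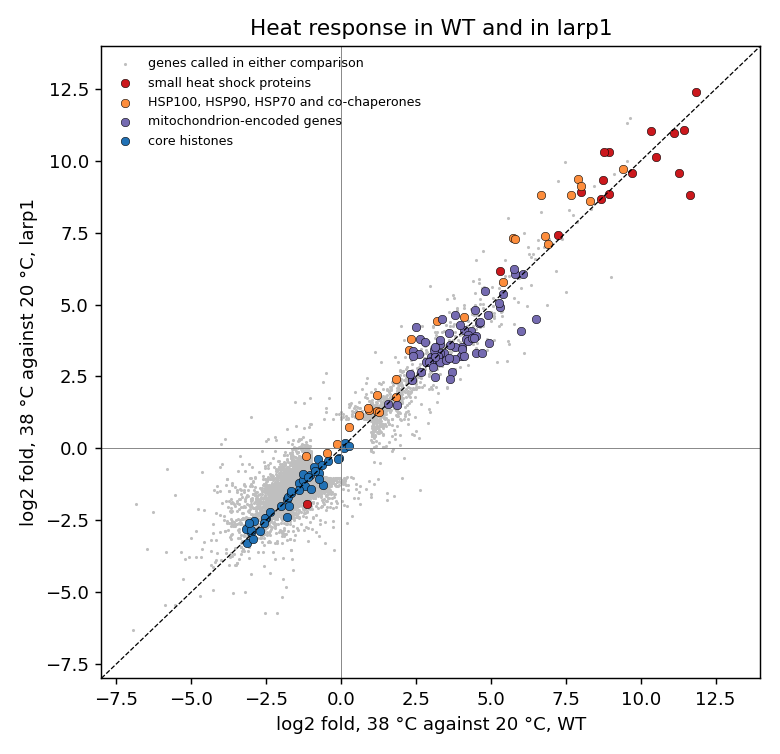
Log2 fold change at 38 °C against 20 °C in WT (horizontal axis) and in larp1 (vertical axis) for genes called in either genotype (grey) and for members of 4 gene lists (coloured); the dashed line marks equal values. Small heat shock proteins reach 11.84 in WT and 12.39 in larp1, and core histones have medians of -1.40 and -1.43.

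The same comparison within larp1 asks whether the mutant shows the heat response. The same classes moved: small heat shock proteins went from 0.00849% to 3.06% of reads and the large chaperones from 0.661% to 8.66%. Of 20475 genes, 857 were at least 2-fold higher and 4051 at least 2-fold lower. HSP22-ER had the highest log2 fold change, 12.39 [11.69, 13.37], and AT1G71000 had 11.49, HSP17.6C-CI 11.07, HSP17.6-CII 11.04 and HSP21 10.96. HSP17.8-CI and HSP17.6A-CI (AT1G59860) both had 10.30, HSP17.7-CII had 10.13 and HSFA7B 10.01. APX2 had 0 reads at 20 °C and was at least 854.6-fold higher.

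On the lower side in larp1, MYB24 was lower by a ratio of 152.1 [27.1, 6033], AT3G45840 by 81.5 [14.4, 3243], AT5G03890 by 45.9 [12.5, 382.3] and the receptor-like protein RLP22 (AT2G32660) by 23.3 [7.79, 114.9]. OFP16 had a log2 fold change of -5.46, AT1G61840 of -4.92, AT2G21210 of -4.53, AT5G66985 of -4.13, and AT1G04360 and AT2G02630 of -4.06 each. Core histones were lower in 27 of 41 and SAUR genes in 31 of 53, with medians of -1.43 each. All 76 mitochondrion-encoded genes compared were higher, with a median of 3.57. Most of these too reached the minimum only in the heated library, and the sum over all mitochondrion-encoded genes went from 52.2 to 591 RPM. Large chaperones were higher in 23 of 27, with a median of 3.79. Abscisic acid and dehydration genes were higher in 4 of 12 and lower in 0. Defence genes were lower in 3 of 6, with PR5 (AT1G75040) at -1.51 and PR2 (AT3G57260) at -1.38. Nuclear photosynthesis genes were lower in 3 of 26 and had a median of -0.56; RBCS1B (AT5G38430), a Rubisco small subunit, had -1.09. The translation, clock and rapid stress medians, -0.37, -0.09 and -0.31, turned positive under TMM and median-of-ratios scaling. TMM scaling gave 1245 higher and 2044 lower genes and median-of-ratios 1324 and 1916, so that higher genes made up 37.9% and 40.9% of the calls in place of 17.5%.

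The responses of both genotypes, which share no library, overlapped widely. Among 19349 genes compared in both, 3122 were lower in WT and in larp1, where independent lists would share 914.1, and 700 were higher in both, where independent lists would share 34.2. No gene was higher in WT and lower in larp1, and 3 went the other way. Pearson's r of the log2 fold changes was 0.926 across genes, which are not independent replicates.

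**Figure D3:**
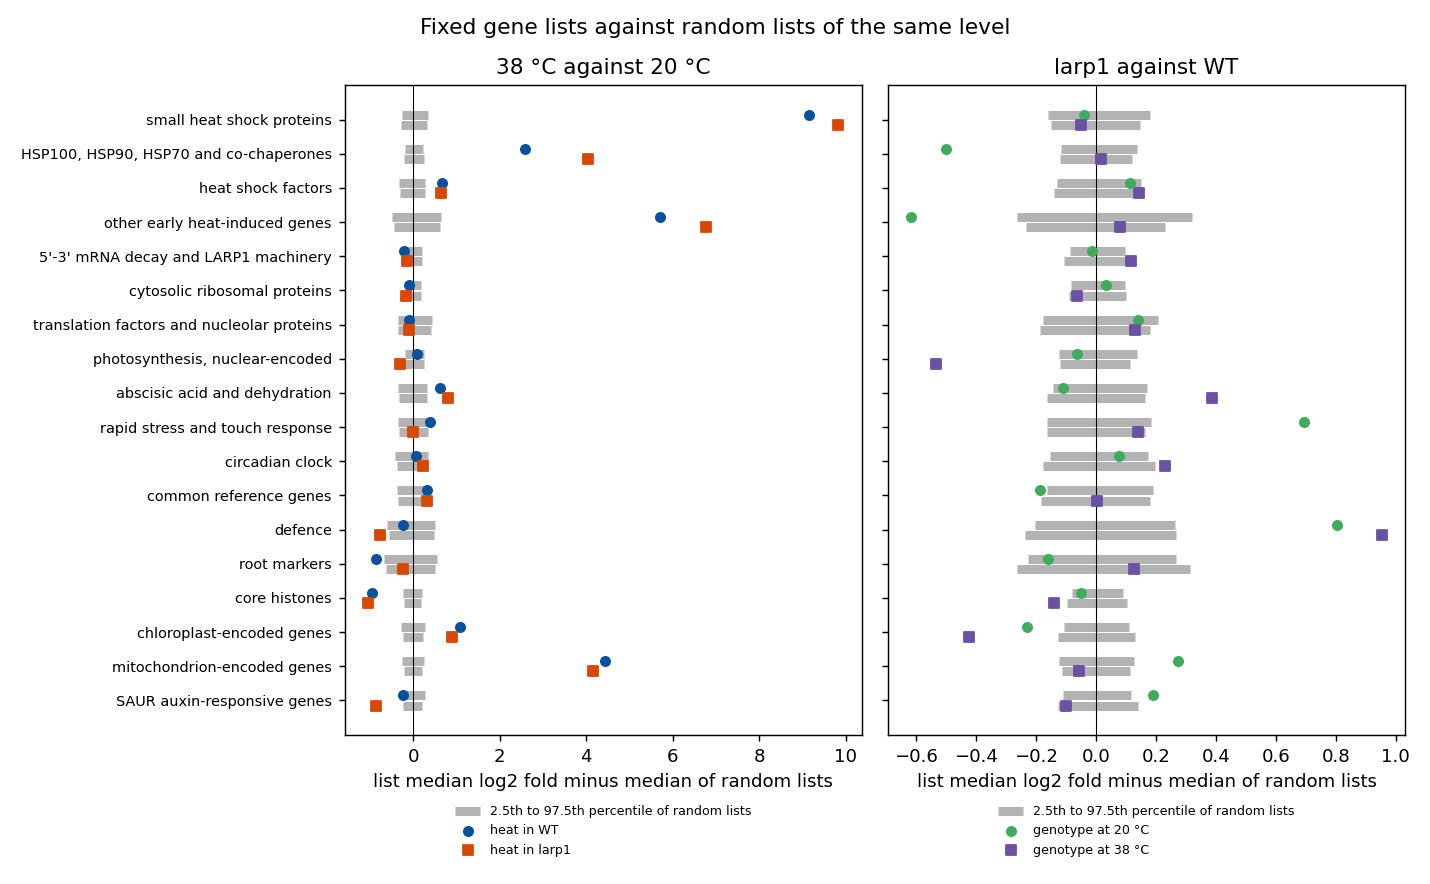
Median log2 fold change of each fixed gene list minus the median of 10000 random lists of the same size and level, for heat in both genotypes (left) and for larp1 against WT at both temperatures (right); grey bars span the central 95% of the random lists. Core histones lie 0.94 and 1.04 below their random lists after heat in WT and in larp1, and the large chaperones lie 0.50 below theirs in larp1 at 20 °C.

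The difference of the heat responses, larp1 minus WT, asks which genes responded otherwise in the mutant. Genes that were lower after heat in WT were as a group less lowered in larp1. Over the 4818 of them compared in both genotypes, the median difference of log2 fold was 0.31, with medians of -1.44 in WT and -1.18 in larp1. Over all 19349 genes the median difference was 0.10, so the excess was 0.21. The excess was 0.12 over genes lower by the mean of both genotypes and absent, at -0.01, over genes chosen in larp1. The median difference of the genes chosen in larp1, 0.0873, turned to -0.0383 under TMM and -0.0255 under median-of-ratios scaling. Single genes past 2-fold were 399 in the positive and 128 in the negative direction; TMM scaling gave 292 and 184 and median-of-ratios 308 and 177, so that positive differences made up 61.3% and 63.5% of the calls in place of 75.7%.

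Among genes with at least 100 reads in at least 1 library of each genotype, the largest positive differences were those of the metacaspase MC8 (AT1G16420), 4.13 [3.19, 5.07], AT3G08870, 3.93 [2.45, 5.42] with 3 reads in WT at 38 °C, ATCSLA15, 3.84, RD29B, 3.14 [2.68, 3.61], and the acetyltransferase NATA1 (AT2G39030), 2.82. MC8 stood at 3.71 and 0.21 RPM in WT and at 8.06 and 8.83 RPM in larp1, at 20 and 38 °C. The abscisic acid and dehydration list had a median difference of 0.91, above all 10000 random lists, with 4 of 12 members past 2-fold. Its members ranged from -0.91 to 3.14, and its median of larp1 against WT was -0.11 at 20 °C and 0.45 at 38 °C. RD29A had 1.31 and COR15A 1.74. Large chaperones had a median difference of 0.57 with 9 of 27 past 2-fold, HSP101 at 1.45 and HOP3 at 1.13, and HSFA2 had 2.49; their levels at 38 °C were alike and those at 20 °C were not. The largest negative differences under the same limit were those of HSP23.6-MTI, -2.82 [-3.42, -2.22], DREB19 (AT2G38340), -2.24, AT3G48240, -2.00, and LBD41 (AT3G02550), -1.92. AT1G06030, with 0 reads in WT at 20 °C, has no place in that order; after heat it was at least 170.8-fold higher in WT and 68.3-fold higher in larp1. Nuclear photosynthesis genes had a median difference of -0.42 and SAUR genes of -0.25. Root markers had a positive difference in all 7 compared, from 0.27 to 0.74, with a median of 0.55 against 0.12 for random lists, although 0 passed 2-fold.

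At 20 °C the comparison of larp1 with WT asks what the mutation changed without heat. Genes higher in larp1 outnumbered those lower, 708 against 100 of 20299 compared. Those higher included the glucosyltransferase UGT73C1 (AT2G36750), at 0.09 RPM in WT and 12.5 RPM in larp1, the transcription factor WRKY59 (AT2G21900), higher by a ratio of 121 [33.3, 1003], and sks8 (AT1G21850) and AT3G29156, with log2 fold changes of 6.57 and 6.48. AT3G22350 had 0 reads in WT and was at least 38.2-fold higher. Pathogenesis-related genes stood higher: in the defence list 3 of 6 were at least 2-fold higher, with PR2 at 18.2 and 132.6 RPM, PR5 at 13.98 and 46.5 RPM, and PR1 (AT2G14610), named after its values were seen, at 24.4 and 52.0 RPM. The list median was 0.82.

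Large chaperone transcripts were as a group lower in larp1 at 20 °C, and small heat shock proteins were divided. Of 27 large chaperones and co-chaperones 9 were at least 2-fold lower and 1 higher, with a median log2 fold change of -0.52, under the lowest of 10000 random lists. HSP101 stood at 43.2 RPM in WT and 16.1 in larp1, and HOP3 at 19.4 and 8.67 RPM. Of 15 small heat shock proteins compared 2 were higher and 2 lower, with a median of -0.06; HSP23.6-MTI had 2.86, HSP17.4-CI 1.72, HSP17.8-CI -1.59 and HSP17.6A-CI -1.49. The factor HSFA2 was lower by -2.54 [-2.75, -2.35]. Rapid stress and touch genes were higher in 3 of 14, with a median of 0.69, ZAT12 at 1.22 and CBF3 at 1.74. Also among the lowest genes were MRD1 (AT1G53480) at -5.40 [-5.70, -5.13], its neighbour HEI10 (AT1G53490) at -4.70, whose entry carries the name of MRD1, the methyltransferase BSMT1 (AT3G11480) at -3.48, and ILL5 at -3.12. Ribosomal protein genes were higher or lower in 0 of 41, with a median of 0.03 that TMM and median-of-ratios scaling turned negative.

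At 38 °C larp1 and WT were compared in the same way. Of 18528 genes 726 were at least 2-fold higher in larp1 and 37 lower. The highest log2 fold changes were those of PUM8 (AT1G22240), by a ratio of 148.9 [26.3, 5918], UGT73C1, 6.07 [4.97, 8.22], WRKY59, by a ratio of 78.1 [26.4, 381.2], AT3G54520, by 53.1 [17.9, 260.1], and MC8, 5.24. The lowest were MRD1, -4.52, HEI10, -3.30, AT4G11211, -2.62, AT4G12490, -2.50, and TCTP (AT3G16640), the translationally controlled tumour protein, -1.98 [-2.01, -1.95]. Large chaperones were higher in 1 of 27 and lower in 0, and the list median was 0.03, which turned negative under TMM and median-of-ratios scaling, as did those of the translation, SAUR, reference and other early heat lists. The small heat shock proteins were higher or lower in 0 of 17. In the defence list 3 of 6 were higher and 1 lower, with PR2 at 2.11, PR5 at 1.22 and VSP1 at 22.63 RPM in WT and 52.07 RPM in larp1. RD29B was higher at 3.31. Nuclear photosynthesis genes had a median of -0.54, under the lowest of the random lists, although 0 of 26 passed 2-fold. TMM scaling moved the median of all genes, 0.14, by -0.15 and gave 581 higher and 69 lower genes; median-of-ratios gave 575 and 72.

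Genotype differences recurred at both temperatures. Of 18314 genes compared at both, 396 were higher in larp1 at 20 and at 38 °C, where independent lists would share 20.2, and 12 were lower at both, where independent lists would share 0.124; of the 65 genes lower at 20 °C, 12 were lower at 38 °C too. None was higher at 20 and lower at 38 °C, and 5 were lower at 20 and higher at 38 °C, where independent lists would share 2.55: NATA1, AT1G30250, AT3G28270, ABCG27 (AT3G52310) and PGL5 (AT5G24420), the last 4 named after their values were seen. Across genes Pearson's r was 0.708 and Spearman's rho 0.399; genes are not independent replicates. Besides LARP1A, MRD1, HEI10, TCTP, AT4G11211 and AT4G12490, the genes lower at both, named after their values were seen, were DI19 (AT1G56280), ARFA1E (AT3G62290), AT3G15356, CYP71B22 (AT3G26200), FLC (AT5G10140) and AT5G41761. TCTP stood at 953.6 and 1189 RPM in WT and at 310.6 and 301.9 RPM in larp1. DI19, a zinc finger protein induced by drought, stood at 335.9 and 447.8 RPM in WT and 121.5 and 153.9 RPM in larp1.

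**Figure D4:**
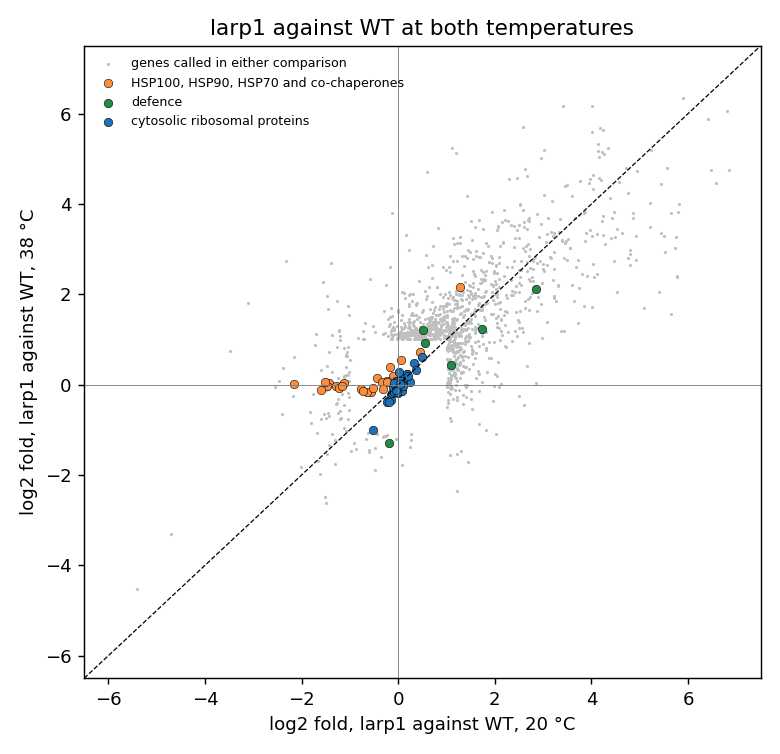
Log2 fold change of larp1 against WT at 20 °C (horizontal axis) and at 38 °C (vertical axis) for genes called at either temperature (grey) and for members of 3 gene lists (coloured); the dashed line marks equal values. Large chaperones have a median of -0.52 at 20 °C and 0.03 at 38 °C, and the defence genes have medians of 0.82 and 1.06.

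The authors' deposited tables list genes by heat response, using gene sums that count repeated entries. The authors' deposited tables hold 4745 genes down in WT, of which 3005 were also down in larp1, and 3705 down in larp1. Of the 4745 genes in the authors' deposited tables, 54 had a fold of at least 1 in larp1, which is 1.14%. The reverse count from the same sums, genes listed as down in larp1 with a fold of at least 1 in WT, was 21 of 3705. Of the genes listed as down in WT, 79.4% were less lowered in larp1, and of those listed as down in larp1, 43.4% were less lowered in WT. For reference, 63.1% of all 19349 genes compared here had a positive difference of heat log2 fold (larp1 minus WT). Choosing a list in 1 genotype also favours genes that happened to be low there. The authors' deposited tables hold 680 genes up in both genotypes.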

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

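The test of carry-over, all tests of the mitochondrial transcripts, the test with drawn reads, the test of root markers and the weighing of variation between libraries or batches were chosen after the results were seen; the tests of regression to the mean in genes chosen in larp1, of scaling for the lowered genes and of a weaker response of larp1 were set before. The differences named next were picked out because WT and larp1 moved in opposite directions after heat; with 1 library per group the difference was not tested against replicates. They were the difference of heat log2 fold (larp1 minus WT) of RD29B, 3.14, of NATA1, 2.82, of COR15A, 1.74, and of FMO1 (AT1G19250), -1.21, the last named after its values were seen. In larp1 the heat log2 folds of COR15A, 0.34, and FMO1, -0.14, did not pass 2-fold, and that of FMO1 turned positive under TMM and median-of-ratios scaling and with the 100 highest genes left out, so its direction there is open. The rapid stress and touch list had medians of 0.09 in WT and -0.31 in larp1, with a median difference of -0.49; TMM and median-of-ratios scaling turned the larp1 median positive.

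Genes lower after heat in WT were less lowered in larp1, by a median of 0.31 against 0.10 over all genes. Reads drawn with a shared heat fold gave an excess of 0.0253 for genes chosen in WT, where 0.21 was observed. That argues against counting noise as the whole cause. For genes chosen by the mean of both genotypes the drawn excess was 0.0043, where 0.12 was observed. That choice favours neither genotype, so a small drawn excess was set in advance there and does not bear on counting noise. The lower of the medians of these genes under TMM and median-of-ratios scaling was 0.13, which argues against scaling as the whole cause. Choosing genes in WT favours those that happened to be low there: for genes chosen in larp1 the median was 0.0873, above the bound of 0.05 set beforehand, but that bound left out the shift of all genes, relative to which it was -0.01, and it was -0.0383 under TMM and -0.0255 under median-of-ratios scaling, so regression to the mean stays open, although deep genes chosen by the mean of both lay 0.10 above all deep genes. Genes higher after heat had a median difference of 0.0352, above the bound of -0.1 set beforehand, and stayed above it relative to all genes, at -0.06, and under TMM scaling, at -0.09 with a spread down to -0.11, which argues against a weaker response of larp1 as the whole cause but does not exclude it as a small part. A different share of root in the pools (root markers 0.55) and variation between single libraries, which could give the 0.21 of genes chosen by the mean of both, cannot be told apart from genotype with 1 library per group.

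Large chaperone transcripts, but not the small heat shock proteins as a group (median of larp1 against WT -0.06), were higher in the WT 20 °C library than in the larp1 20 °C library. Reads carried over from the heated WT library would have to make up 1.197% of it (median over 9 chaperones), whereas HSP22-ER allows at most 0.0445%, and 15 of 17 small heat shock proteins had ratios under the share needed, which argues against carry-over. The chaperone median of larp1 against WT was 0.0273 at 38 °C. A difference between single plant batches may also account for the pattern; it cannot be told apart from genotype without replicate libraries.

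Mitochondrion-encoded transcripts were higher after heat in both genotypes. The medians given next rest mostly on genes that reached the minimum of reads only in the heated library. The sums over all these genes, which need no minimum, went from 40.4 to 503.9 RPM in WT and from 52.2 to 591 RPM in larp1. A lower share of nuclear mRNA would raise chloroplast-encoded transcripts alike, but the mitochondrial median exceeded theirs by at least 3.21, which argues against it as the whole cause. The lowest mitochondrial median under TMM and median-of-ratios scaling was 3.96. Both scalings raised all heat folds, so the median could not fall and this test cannot decide on scaling. Relative to random lists of the same level, a position that no scaling changes, the mitochondrial median was 4.44 higher in WT and 4.17 higher in larp1. Residual organelle DNA stays open: the chloroplast median was at most 0.36, but it lay 1.08 in WT and 0.91 in larp1 above random lists of the same level and was 0.86 in WT under TMM scaling. Also open, and not tested, are changes in mitochondrial transcript processing or polyadenylation, in nuclease depletion between libraries, and in transcript amount.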

How the results depend on the processing

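No paired analysis was possible because each group has 1 library and the labels hold no replicate numbers, and leaving out a library would remove a group. A fit that takes the genotypes, or the temperatures, as replicates of each other was not made: its residual would hold any true difference of heat responses together with the variation between libraries. The authors' gene sums, the highest exon entry, the choice by the mean with at least 500 reads, and both choices of genes together with a scaling were added after seeing the data. Counts moved by over 1.5 times as follows; where scaling or a read minimum sets them, it acts by its own construction, and for the pseudocount the cause was not tested. TMM scaling gave 1332 higher and 2183 lower genes for heat in WT, 2044 lower for heat in larp1 and 69 lower for larp1 at 38 °C; median-of-ratios gave 1389 and 2100, 1324 higher and 1916 lower, and 72. A minimum of 10 reads gave 1123 higher and 258 lower genes for larp1 at 20 °C, 1212 and 125 at 38 °C, and 627 and 282 for the difference of heat responses; no minimum gave 1169 and 340, 1287 and 144, and 695 and 355. A pseudocount of 0.5 RPM gave 66 lower genes at 20 °C and 157 and 49 for the difference. The overlap of lowered genes was 1029 at 3-fold. The median difference over genes lower after heat in WT, 0.31, was 0.29 with TMM, 0.33 with a minimum of 10 reads, 0.34 with none, 0.26 with the pseudocount and 0.32 with the highest exon entry alone; it was 0.0873 for genes chosen in larp1, 0.21 by the mean of both, and 0.19 by that mean with at least 500 reads. For genes chosen in larp1 it reversed to -0.0383 with TMM and -0.0255 with median-of-ratios, where all genes shifted by -0.11 and -0.10; by the mean of both it was 0.13 and 0.14. The median difference of chloroplast-encoded genes reversed to 0.0236 with a minimum of 10 reads and 0.0316 with none, and that of mitochondrion-encoded genes to 0.0566 with none and 0.0304 with the pseudocount, the cause not tested. The other 66 counts stayed within 1.5 times. Of the list medians 454 moved by less than their members' counting interval and 172 by more; 48 of these, all of lists within the central 95% of random lists, changed sign. Of the values of named genes' folds called at least 2-fold, 1488 stayed within their counting interval, 423 did not and 0 changed sign; of 2457 values of their folds under 2-fold or not called, 142 changed sign. Depth limits genes with few reads: 3 reads are 0.0403 to 0.0704 RPM.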

Other observations

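The families named here, out of 208 found in the deposited descriptions, and the test of ribosomal protein genes were chosen after the values were seen. Genes described as cysteine-rich receptor-like kinases were higher in larp1 in 14 of 34 at 20 °C, with a median log2 fold of 0.52 against 0.05 for random lists, and in 13 of 31 at 38 °C, with a median of 0.69 against 0.15. WRKY transcription factors were higher in 11 of 60 and 10 of 51, with medians of 0.36 and 0.47, and lower in 0 at both temperatures. FMO1 and ALD1 (AT2G13810), which act in systemic acquired resistance, were named after their values were seen: FMO1 stood at 2.01 RPM in WT and 45.4 RPM in larp1 at 20 °C, and ALD1 at 1.04 and 21.7 RPM. After heat, genes of the cysteine and histidine-rich C1 domain family were lower in 44 of 55 in WT and 48 of 69 in larp1, and mitochondrial transcription termination factor family genes in 18 of 26 and 17 of 26.

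The number of exon entries went with the heat response, in a test set before its result was seen. Genes with 1 distinct entry had a median log2 fold after heat of -1.02 in WT against -0.59 for random lists of the same level, and of -0.86 against -0.49 in larp1. Of these genes 50.7% were at least 2-fold lower in WT, against 9.63% of genes with 10 or more entries. They were also more often higher, in 219 of 3085 against 89 of 3893, so they varied more in both directions. The value is consistent with the hypothesis that transcripts of few exons are lowered more by heat; transcript length was not separated from exon number.

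A second hypothesis, written after the values of TCTP were seen, was that ribosomal protein and translation factor mRNAs are lower as a class in larp1. The median genotype log2 fold of ribosomal protein genes at 20 °C was 0.0341, at the 75.7th percentile of random lists, and -0.01 at 38 °C, at the 9.25th, so the class was not lower and TCTP stood apart from it.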
